A study of Mus musculus with 8 samples.

How the data were processed

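RNA was measured in 8 libraries of sorted CD8+ T cells from mouse tumours, 4 from Pglyrp1 knockout (KO) mice and 4 from wild-type (WT) mice. Per the labels' protocols, MC38-OVA cells, a mouse colon carcinoma line that expresses the model antigen ovalbumin, were injected under the skin of the flank. Each library was made from 1000 living cells positive for CD45, TCRβ and CD8, with a modified SMART-Seq2 method (full-length cDNA) and Nextera XT, and sequenced in pairs of 38 bases. The KO animals carry the B6.129S4-Pglyrp1tm1.1Lky/J allele and the WT animals are C57BL/6J, per the labels' protocols. The series' design text counts 4 mice per genotype, so p-values measure the spread between mice, each seen in 1 library.

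The deposited table holds 20029 genes by symbol, of which 3004 are at 0 in all 8 libraries. Its values are a score, named by the authors as a TPM-normalized count: whole numbers that sum to between 2223162 and 3342847 per library, so they are neither raw counts nor TPM as deposited. Low values come in steps that depend on gene length. In genes with transcripts of 600 to 800 bases, 51.8% of values from 1 to 9 were multiples of 3, where 33.3% would be by chance, and at 800 to 1000 bases 74.2% were multiples of 2, where 44.4% would be. RSEM 1.3.3 and the mm10 build are named in the submitters' processing notes. The aligner, the annotation and the step that scaled and rounded the values are not given in the sources used here. No read counts were at hand, so the depth of each library is unknown and no counting intervals are given. One unit of the deposited score was worth 0.299 to 0.450 TPM after rescaling.

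Each library was rescaled to a sum of 1000000, called TPM from here on, and log2(TPM + 1) was used for every test. The planned test assumed TPM and was kept after this rescaling. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Genes with at least 1 TPM in at least 4 libraries were tested, 10732 in all, with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean trend, group as the only term) and Benjamini-Hochberg adjustment at 0.05. The comparison was KO against WT. Gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The mean log2(TPM + 1) of each list per library was compared by a two-sided exact permutation test over 70 assignments, whose smallest p is 0.0286. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

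The lists, the named-gene rule and the other settings were fixed before the data were examined. The rule names Pglyrp1 and, per direction, up to 12 genes with the largest fold change among those that pass and whose groups do not overlap. Places left open are filled by the smallest unadjusted p among genes with a mean of at least 5 TPM and groups that do not overlap. Clone and model names, pseudogenes and receptor segments are skipped. Each list then adds every member that passes, up to 4, or else its 2 members of smallest p. Of 669 list entries in 36 lists, 638 matched the table, 9 of them by another symbol. The mitochondrially encoded list had no match and was not analysed here. Of the table's symbols, 18495 were found in the reference annotation directly and 19904 with synonyms. Coordinates are those of the mm10 annotation, 1-based.

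The pipeline was tested on simulated data for this comparison, with 200 changed genes among 10732 in each of 10 runs. It called 45.9% of genes changed by 1 on the log2 scale, 90.8% at 2, 98.0% at 3 and 99.2% at 4, and 5.65% of its calls were false. A list shifted by 0.7 was called in 20 of 20 runs with the preset correlation, beside 2 of 680 unshifted lists. With the estimated correlation it was called in 16 of 20 runs, beside 0 of 680. Genes in all these simulations varied independently, with no structure shared by samples. In the data the estimated correlation within a list reached 0.849, for ribosomal proteins. The simulated rates therefore need not hold for the genes and lists measured here. The alternatives varied the pseudocount, the filter, the scaling, the limma options and a marker covariate, and left out each library in turn. Settings that leave out KO libraries 3 and 4, WT libraries 6 and 9, or both pairs were added only after the data were seen.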

Results

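Gene expression was measured in CD8+ T cells sorted from subcutaneous MC38-OVA colon carcinomas of Pglyrp1 KO mice (n = 4, replicates 1 to 4) and WT mice (n = 4, replicates 6 to 9). The comparison asks how loss of Pglyrp1, a secreted protein that binds bacterial peptidoglycan, alters the transcriptome of tumour-infiltrating CD8+ T cells. The deposited values summed to between 2223162 and 3342847 per library, and 11935 to 13300 genes were above 0. Pearson correlations of log2(TPM + 1) were 0.942 to 0.972 among KO libraries, 0.957 to 0.976 among WT libraries and 0.928 to 0.973 between the groups.

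Pglyrp1 itself (chromosome 7, 18884690 to 18890438) was listed at 0 in all 4 KO libraries and at 123, 210, 208 and 153 TPM in WT libraries 6 to 9 (limma adjusted p = 2.93e-07; exact permutation p = 0.0286, the smallest possible). Plaur (chromosome 7, 24460937 to 24475970), which encodes the urokinase receptor, rose from 3.24 ± 2.06 TPM in WT to 80.7 ± 18.8 in KO cells (SD, n = 4 each), a log2 fold change of 4.37 (SE 0.36, limma adjusted p = 0.00234). Mir684-1 is a microRNA precursor gene of 86 bases on chromosome 2, a length at which few reads give a large TPM. It was listed at 0 in all WT libraries and at 106, 41.1, 336 and 948 TPM in KO libraries 1 to 4 (limma adjusted p = 0.0133). Large values in some libraries and 0 in others were common among such genes. Of 59 microRNA precursor genes in the table, 31 were above 0 in at least 1 library and 19 in 1 library only. Their values above 0 had a median of 378.5 in the deposited score. Only Mir684-1 was above 0 in every KO library and at 0 in every WT library. Pglyrp1, Plaur and Mir684-1 were the 3 genes past the limma threshold among 10732 tested, 2 higher and 1 lower in KO. At an unadjusted p under 0.05 there were 974 genes, 645 higher and 329 lower, where 536.6 would be expected by chance if genes were independent. Other splits of the 8 libraries into 4 and 4 gave as many as 2244, 1618, 1226 and 1202 genes. The counts for KO against WT depended on single libraries. There were 340 higher and 276 lower without KO library 4, 367 and 258 without KO library 3, and 433 and 249 without WT library 6. The number higher rose in other cases: 905 and 382 without KO library 1, and 789 and 280 without KO library 2. It also rose without WT library 7 (891 and 360) and WT library 8 (805 and 296). Without WT library 9 there were 514 and 367. The balance turned without KO libraries 3 and 4 (196 and 282 of 11320 genes). It also turned without WT libraries 6 and 9 (425 and 641 of 11718) and without both pairs (381 and 965 of 10867). The balance of directions also depended on scaling. There were 666 higher and 418 lower with median-ratio scaling, and 565 and 535 with quantile normalization. With ribosomal protein genes and the 20 most abundant genes removed there were 536 and 629. Adding the myeloid and stromal covariate to the model gave 164 and 270. Groups did not overlap for 281 genes higher in KO (2.62%) and 258 lower (2.40%), where chance gives 1.43% in each direction. Plaur had an adjusted p of 0.0593 without KO libraries 3 and 4, and Mir684-1 lost its call in several settings, among them a pseudocount of 5 (adjusted p = 0.143). The number of genes past the threshold was 9 without KO library 2 and 5 without KO library 1. It was 10 without KO libraries 3 and 4 and WT libraries 6 and 9. In each of these settings 3 were the genes called with all libraries. The others were Ccl12, Snora24, Irg1, Clec4n, Cxcl9 and Ccl7 without KO library 2, and Rnu12 and Cox7a1 without KO library 1. Without both pairs they were Snord104, Mir682, Snora41, Mir5117, Mir546, Hist1h2an and Hist1h3c.

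**Figure D1:**
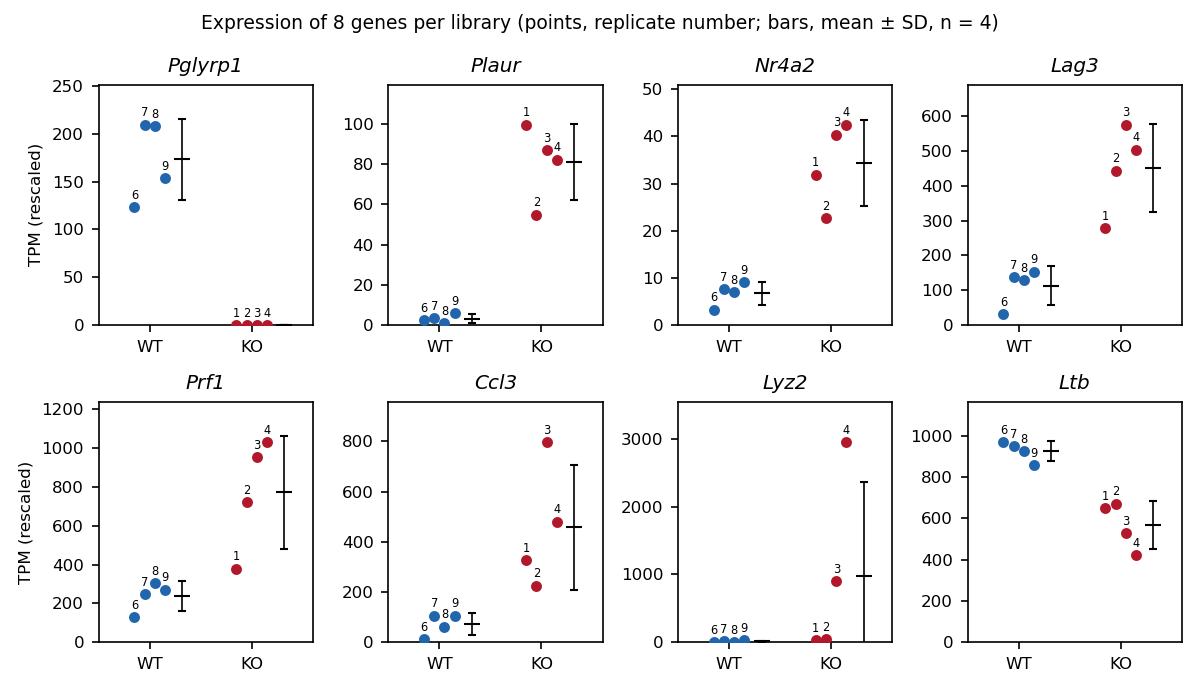
Expression of 8 genes in TPM (vertical axes, linear, from 0) in WT and KO libraries; points are libraries with their replicate number, bars are mean and SD (n = 4). Pglyrp1 is at 0 in every KO library, the 4 Plaur values of KO libraries lie between 54.7 and 99.5 TPM, and Lyz2 is high in KO libraries 3 and 4.

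The rule of 12 genes per direction left places for 10 higher and 12 lower genes that did not pass the adjusted threshold. Nr4a2, an orphan nuclear receptor induced by T cell receptor signals, had 34.4 ± 9.04 TPM in KO and 6.72 ± 2.47 in WT cells (SD, n = 4; log2 fold change 2.22, SE 0.31, limma adjusted p = 0.101). Zbtb32, a zinc finger repressor, had 96.3 ± 37.6 and 20.0 ± 10.5 TPM, and Cblb, a ubiquitin ligase that restrains T cell activation, had 69.1 ± 6.74 and 39.0 ± 5.99 TPM. Ramp3 (log2 fold change 2.57), Mt2 (2.59), Ndrg1 (1.76), Abcb9 (1.04), Got1 (0.99), Vimp (0.74) and Snrpd2 (0.68) were also named as higher. Groups that do not overlap are a condition of the rule. On the other side, Ltb, the lymphotoxin beta gene, had 568 ± 116 TPM in KO and 925 ± 49.4 in WT cells (log2 fold change -0.73, limma adjusted p = 0.328). Prkd2 (log2 fold change -1.06), Igflr1 (-1.03), Btbd6 (-1.21), Acss2 (-0.94), Gramd1a (-0.90), Arhgef1 (-0.89), Sun2 (-0.89), Fam78a (-0.83), Abhd8 (-0.81), Orai2 (-0.65) and Kif21b (-0.65) had lower values in KO, with limma adjusted p from 0.177 to 0.327.

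Inhibitory receptor genes had higher values in KO cells: 17 of 18 measured members had a positive fold change. Of the 20 in the table, 11 were higher in both KO 3 and KO 4, the libraries with high myeloid markers, than in each of the other 6 libraries, as were 14.2% of all genes tested. Lag3, a receptor that binds MHC class II, had 450 ± 126 TPM in KO and 113 ± 55.7 in WT cells (SD, n = 4; log2 fold change 2.17, SE 0.48). Tigit had 415 ± 37.6 and 200.2 ± 115 TPM, Havcr2 (Tim-3) 144 ± 48.8 and 55.2 ± 37.6, and Cd200 18.6 ± 11.8 and 4.35 ± 2.12. Pdcd1 (PD-1) had 456 ± 129 and 224 ± 137 TPM, with overlapping groups. None passed over all genes tested, and 5 passed when adjusted over the list alone (Cd200, Cd274, Havcr2, Lag3 and Tigit). The list mean was 6.02 ± 0.32 in KO and 5.04 ± 0.57 in WT cells on the log2 scale, with the groups apart (exact permutation p = 0.0286; 0.143 adjusted over the lists). Camera called the list with the preset correlation (adjusted p = 5.70e-07), with an adjusted p = 0.399 with an estimated correlation. The difference of the list mean was 0.71 without KO libraries 3 and 4, 0.50 without WT libraries 6 and 9, and 0.23 without both pairs.

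Genes tied to terminal exhaustion followed the same direction, with a positive fold change for all 18 measured members. Besides Nr4a2, Rgs16, a regulator of G protein signalling, had 238 ± 71.0 TPM in KO and 55.8 ± 41.4 in WT cells, and Irf4 25.2 ± 5.34 and 9.72 ± 6.22 (SD, n = 4). Of these, 0 passed over all genes tested and 3 (Irf4, Nr4a2 and Rgs16) when adjusted over the list alone. The list mean was 5.77 ± 0.22 in KO and 4.87 ± 0.65 in WT cells (camera adjusted p = 1.07e-06; adjusted p = 0.399 with an estimated correlation). The call was lost without KO libraries 3 and 4 and WT libraries 6 and 9 (adjusted p = 0.148). The list means of WT libraries 6 to 9 were 4.02, 5.46, 5.28 and 4.70. Of 20 genes, 7 were higher in both KO 3 and KO 4 than in each other library. The difference of the list mean was 0.91 with all libraries, 0.72 without KO 3 and 4, 0.40 without WT 6 and 9, and 0.21 without both pairs. In the last setting 9 of 18 members were positive.

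Prf1, the pore-forming protein of cytotoxic granules, had 771 ± 292 TPM in KO and 239 ± 76.7 in WT cells (SD, n = 4; log2 fold change 1.66, SE 0.36), and was the one of 18 measured cytotoxic members that passed when adjusted over the list alone; 0 passed over all genes. Gzmb had 2246, 2804, 2636 and 2385 TPM in KO libraries 1 to 4 and 357, 1567, 2644 and 528 in WT libraries 6 to 9. The cytotoxic list was called by camera (adjusted p = 0.00467, and 0.537 with an estimated correlation), and not without WT libraries 6 and 9 (adjusted p = 0.805). Its list mean was 7.67 to 8.31 in KO libraries and 6.83 to 7.97 in WT libraries (exact permutation p = 0.171). Among 15 measured cytokine and chemokine genes, Ccl3 (458 ± 250 TPM in KO, 72.6 ± 44.2 in WT), Ccl4 and Ifng (171 ± 67.9 and 49.1 ± 42.4) had higher values and Ltb lower. These 4 passed when adjusted over the list alone, and 0 over all genes (camera adjusted p = 0.0390; adjusted p = 0.537 with an estimated correlation). The cytokine list kept its call in 15 of 22 settings and lost it without KO library 1 (adjusted p = 0.190), WT library 6 or WT library 9, and without both WT 6 and 9 (0.794). Of 14 costimulatory receptors, Tnfrsf9 (4-1BB, 313 ± 49.9 and 101 ± 51.5 TPM) and Tnfrsf4 (OX40, 112 ± 44.5 and 41.5 ± 20.5) passed when adjusted over the list alone and 0 over all genes, and the list was not called (camera adjusted p = 0.353).

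WT libraries 6 and 9 stood apart from WT libraries 7 and 8 in genes of naive and memory T cells. Ccr7, a lymph node homing receptor, was at 769 and 652 TPM in WT libraries 6 and 9, 188 and 134 in WT libraries 7 and 8, and 84.2 to 443 in KO libraries. Tcf7, which encodes the transcription factor TCF1, was at 329 and 310 TPM in WT 6 and 9 and at 64.3 and 100.01 in WT 7 and 8. Ribosomal protein genes took 36.7% and 36.3% of the TPM in WT 6 and 9, and 20.3% to 29.7% in the other libraries. The stem-like, naive and memory list was lower in KO by camera (16 of 20 measured members negative, 0 passing over all genes or when adjusted over the list alone; adjusted p = 0.0119; adjusted p = 0.640 with an estimated correlation). Its list mean had an exact permutation p of 0.629. Without WT libraries 6 and 9 the list was higher in KO, by 0.40 relative to other genes (camera adjusted p = 0.0138). It was higher by 1.01 without KO 3 and 4 as well. The call was lost without any 1 of KO 3, KO 4, WT 6 and WT 9 (adjusted p = 0.0543, 0.452, 0.457 and 0.371). Of 15 TGF-beta signalling genes, 12 were negative and 1, Ski, passed when adjusted over the list alone (0 over all genes; 8.56 ± 1.63 TPM in KO, 15.02 ± 1.46 in WT; camera adjusted p = 8.33e-04; adjusted p = 0.325 with an estimated correlation). The TGF-beta call was lost with the myeloid and stromal covariate (adjusted p = 0.134), without KO 3 and 4 (0.0613) and without both pairs (0.242).

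**Figure D2:**
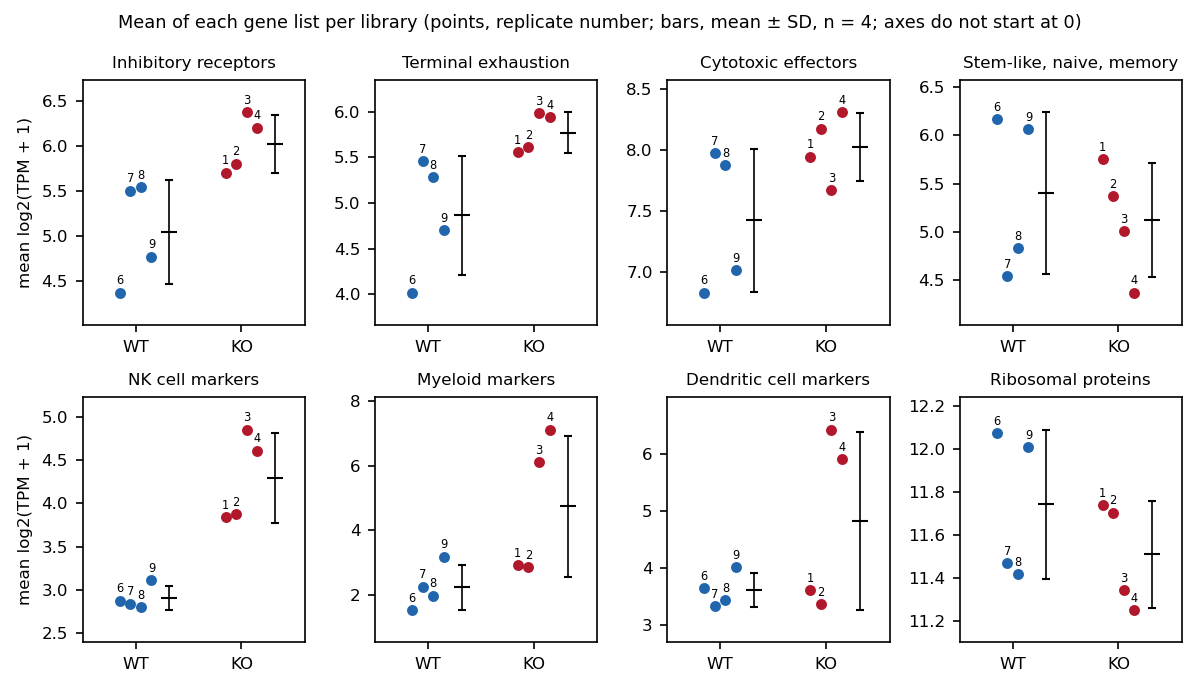
Mean log2(TPM + 1) of 8 gene lists (vertical axes, which do not start at 0) in WT and KO libraries; points are libraries with their replicate number, bars are mean and SD (n = 4). Inhibitory receptor means are 5.70 to 6.37 in KO and 4.37 to 5.54 in WT libraries, and myeloid marker means are high in KO libraries 3 and 4.

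Markers of other cell types differed between libraries within both groups. Lyz2, the macrophage lysozyme, was at 32.2, 47.2, 902 and 2952 TPM in KO libraries 1 to 4 and at 0 to 31.1 TPM in WT libraries. Of 20 myeloid markers in the table, 18 were higher in both KO 3 and KO 4 than in each of the other 6 libraries, as were 14.2% of all genes tested (3.57% by chance). Cd74, the MHC class II invariant chain, was at 1442 and 1610 TPM in KO 3 and 4 and at 40.03 to 256 TPM in the other libraries. The myeloid list mean was 4.75 ± 2.19 in KO and 2.23 ± 0.70 in WT cells (SD, n = 4; exact permutation p = 0.0857; camera adjusted p = 1.07e-06; adjusted p = 0.537 with an estimated correlation). Of its 15 measured members, 0 passed over all genes and 8 when adjusted over the list alone, 7 higher and 1, Apoe, lower. The list mean of B and plasma cell markers (4 measured members) was 3.11 and 2.97 in WT 6 and 9. It was 1.42 and 1.47 in WT 7 and 8, and at most 2.84 in KO libraries. Cd79b was at 34.1 and 27.9 TPM in WT 6 and 9 and at 7.20 and 7.99 in WT 7 and 8. The mean of erythroid and platelet markers (4 measured members) was 5.80 in KO 1, 6.49 in KO 4, 5.60 in WT 9 and 0.550 to 2.56 elsewhere. Camera called neither list.

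The list mean of natural killer cell markers was higher in every KO library than in every WT library. It was 4.29 ± 0.51 in KO and 2.91 ± 0.14 in WT cells (SD, n = 4). The exact permutation p was 0.0286 (0.143 adjusted over the lists). Single members had groups apart in this way for 4 of 13. Of the 14 in the table, 5 were higher in both KO 3 and KO 4 than in each other library. Fcer1g, at 77.3, 65.9, 996 and 1314 TPM in KO libraries 1 to 4, is also on the myeloid list. All 13 measured members were positive, 0 passed over all genes tested, and 7 passed when adjusted over the list alone (Fcer1g, Kit, Klra7, Klra9, Klrb1c, Ncr1 and Tyrobp). Klra7, a Ly49 receptor, had 41.6 ± 21.2 TPM in KO and 13.7 ± 3.81 in WT cells, and Tyrobp, an adaptor also abundant in myeloid cells, was at 83.2, 84.9, 1280 and 1291 TPM in KO libraries 1 to 4 and 23.3 to 40.6 in WT libraries. This list alone was called with an estimated correlation as well (adjusted p = 0.0482; preset correlation, adjusted p = 1.07e-06). CD4 and regulatory T cell markers were also higher (3.28 ± 0.16 and 2.52 ± 0.31, exact permutation p = 0.0286). The camera adjusted p was 0.0119, and 0.399 with an estimated correlation. At the preset correlation the list was called in 17 of 22 settings (largest camera adjusted p 0.106). Among the losses were those without KO library 2 (adjusted p = 0.0594) and WT library 6 (0.0623). Cd4 was at 4.50, 4.84, 66.7 and 15.6 TPM in KO and 0.393 to 2.25 in WT libraries. Cd8b1 had 1183 ± 134 TPM in KO and 1538 ± 180 in WT cells, with limma adjusted p = 0.502. The Y-linked gene Eif2s3y was at 72.5 ± 3.71 and 70.7 ± 9.47 TPM. Over all 35 lists, camera called 21 with the preset correlation, 17 higher and 4 lower in KO, and 1 with the estimated correlation. Other splits of the 8 libraries into 4 and 4 gave up to 18 lists with the preset correlation.

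The genes named by rank were unevenly placed in the genome, a comparison made after their values were seen. Of the 24 genes besides Pglyrp1, 8 lay on chromosome 7 and 7 within 15 Mb of Pglyrp1, a region that holds 2.28% of the tested genes. Plaur lies 5.58 Mb, Snrpd2 0.265 Mb, Prkd2 2.04 Mb, Arhgef1 6.02 Mb, Igflr1 11.7 Mb, Zbtb32 11.7 Mb and Gramd1a 12.2 Mb from it. Within 10 Mb on either side, 12 of 151 genes other than Pglyrp1 had an unadjusted p under 0.01 (7.95%), against 2.16% of the genes elsewhere (odds ratio 3.92, 95% interval 1.95 to 7.20, Fisher's exact p = 1.44e-04). The share was 12.7% within 5 Mb, 7.79% within 15 Mb and 7.25% within 20 Mb. Neighbouring genes are not independent.

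**Figure D3:**
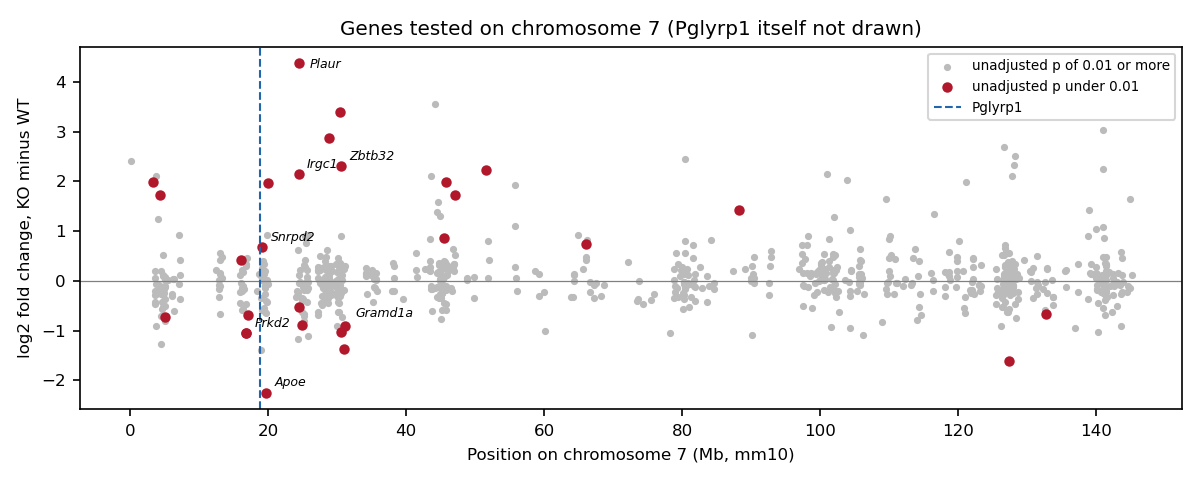
Log2 fold change of KO against WT (vertical axis) of the genes tested on chromosome 7 by position in Mb (horizontal axis, mm10); red points have an unadjusted p under 0.01, grey points do not, and the dashed line marks Pglyrp1. Pglyrp1 itself is not drawn. Of the 151 other genes within 10 Mb of the line, 12 are red, 6 above 0 and 6 below.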

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

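The test for a lone sample in a group was set before the data were examined. It marked 12 of 258 groups of 4 libraries, where chance would mark about 1 in 20, or 12.9, so the number of marks is no more than chance gives.

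In each case the gap from 1 library to the nearest of its group was large relative to the group's range, which for Irf8 was narrow. Among WT libraries, Ramp3 was at 15.7 TPM in WT 7 (others 3.82 to 4.33), Mt2 at 3.15 TPM in WT 9 (7.29 to 8.13), Arhgef1 at 86.5 TPM in WT 9 (136 to 138), Irf8 at 32.5 TPM in WT 6 (35.01 to 35.4) and Ndufs6 at 153 TPM in WT 8 (111 to 116). Pf4, a platelet gene, was at 11.4 TPM and Fn1 at 1.18 TPM in WT 9, and both were listed at 0 in the other WT libraries. The list mean of CD4 and regulatory T cell markers was 2.06 in WT 6 (2.62 to 2.71 in the others, log2 scale). Among KO libraries, Prkd2 was at 43.7 TPM (29.6 to 31.98), Cd79b at 16.3 TPM (5.89 to 6.28) and Areg at 31.5 TPM (3.89 to 5.44) in KO 1, and Fn1 at 69.4 TPM in KO 4 (1.04 to 5.09).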

How the results depend on the processing

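The settings that leave out KO libraries 3 and 4, WT libraries 6 and 9, or both were chosen after the data were seen. No paired analysis was possible because the KO libraries are numbered 1 to 4 and the WT libraries 6 to 9, so no numbers are shared. Pglyrp1 kept its direction and its call in all 22 settings, with a fitted log2 difference of -7.56 to -7.31 when 1 library was left out, a value that depends on the pseudocount. The number of genes past the threshold was 2 to 9 with 1 library left out: 5 without KO replicate 1 and 9 without KO replicate 2. It was 5 without KO 3 and 4, 5 without WT 6 and 9, and 10 without both. Plaur passed in 21 of 22 settings. Mir684-1 lost its call with a pseudocount of 5, without KO replicate 3, without each WT library in turn and without WT 6 and 9 (adjusted p from 0.0567 to 0.168). The log2 fold change of Dusp2 was -3.16 without WT 6 and 9, where it passed (adjusted p = 0.0391). The number of lists called was 16 to 24 with 1 library left out, 12 with the myeloid and stromal covariate, 12 without WT 6 and 9, 9 without both pairs, and 1 each with an estimated correlation, directional fry and mixed fry. Of the 13 lists of other cell types, RNA quality and animal sex, 2 to 3 reached the smallest exact p with 1 library left out. Inhibitory receptors and natural killer markers were called in all 22 settings at the preset correlation (largest adjusted p 0.00824 and 0.00159), but with an estimated correlation the inhibitory receptor list had an adjusted p = 0.399. Mean differences of lists relative to other genes turned in several settings, and the cause was not tested. They were, with the covariate, 0.037 for ribosomal proteins, -0.22 for dendritic cell markers, 0.28 for stem-like genes and 0.036 for T cell receptor components. Without KO 3 and 4 they were 0.0062 for ribosomal proteins, -0.092 for dendritic cell markers, 0.19 for stem-like genes and -0.44 for type I interferon genes. Without WT 6 and 9 they were -0.053 for apoptosis, -0.43 for cell cycle, 0.029 for ribosomal proteins, -0.048 for short-lived effector and 0.40 for stem-like genes. Without both pairs they were -0.44 for cell cycle, -0.029 for cholesterol synthesis, 0.41 for ribosomal proteins, -0.29 for short-lived effector, 1.01 for stem-like and -0.81 for type I interferon genes, and the median of all genes was -0.11. With a mean of at least 10 TPM required, tumour and epithelial markers were at -0.15. Depth is unknown, so its limit on low genes could not be given.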

Other observations

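Every explanation below was tested only after the pattern was seen, and the bounds that decide each test were also set with the values already known.

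Several lists not described above were called by camera with the preset correlation and not with an estimated one. Genes of peptidoglycan recognition and bacterial sensing had a list mean of 5.36 ± 1.40 in KO and 3.67 ± 0.40 in WT cells (SD, n = 4; exact permutation p = 0.0286, 0.143 adjusted over the lists; camera adjusted p = 0.0205; adjusted p = 0.537 with an estimated correlation). Its 3 members that passed when adjusted over the list alone were Lyz1, Lyz2 and Tyrobp, genes abundant in myeloid cells, and 10 of its 16 genes were higher in both KO 3 and KO 4 than in each other library. Glycolysis and hypoxia genes were positive for 22 of 23 measured members (adjusted p = 1.50e-06; adjusted p = 0.537 with an estimated correlation), with Slc16a3, a lactate exporter, at 67.3 ± 24.9 TPM in KO and 22.6 ± 23.1 in WT cells (SD, n = 4). The glycolysis call was lost without WT libraries 6 and 9 (camera adjusted p = 0.370). The list mean of glycolysis genes had an exact permutation p of 0.229. Interferon gamma response genes were positive for 20 of 24 (adjusted p = 1.58e-04; 0.537 with an estimated correlation), and Gbp2 (264 ± 71.9 and 115 ± 38.9 TPM) passed when adjusted over the list alone. Mt1 and Mt2, metallothioneins that bind zinc, passed when adjusted over their list of 7 alone, with Mt1 at 202 ± 111 and 48.6 ± 35.5 TPM. None of these genes passed over all genes tested. The peptidoglycan call held in 18 of 22 settings, and the glycolysis, interferon gamma and metallothionein calls in 20 each.

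The other lists called with the preset correlation are given by the number of members in each direction. Oxidative phosphorylation genes were positive for 29 of 33 members (adjusted p = 8.28e-04; adjusted p = 0.537 with an estimated correlation) and cholesterol and fatty acid synthesis genes for 20 of 24 (adjusted p = 0.00467; 0.537 estimated). Short-lived effector genes were positive for 15 of 18 (adjusted p = 0.00643; 0.537 estimated), apoptosis and survival genes for 16 of 20 (0.0437; 0.617 estimated), and MC38 tumour and epithelial markers for 7 of 8 (0.0221; 0.418 estimated). Dendritic cell markers were positive for 11 of 12 (0.0119; 0.537 estimated). Ribosomal protein genes were negative for 42 of 42 (1.69e-06; 0.579 estimated) and T cell receptor components for 12 of 18 (0.0243; 0.617 estimated). Among these lists, the exact permutation p of the list mean ran from 0.0857 for oxidative phosphorylation to 0.4 for T cell receptor components. Camera called these lists, counted in either direction, in part of the 22 settings. Apoptosis was called in 13, MC38 tumour markers and T cell receptor components in 16 each, and short-lived effector genes and dendritic cell markers in 17 each. Oxidative phosphorylation and cholesterol synthesis were called in 18 each, and ribosomal proteins in 18 of 21. The ribosomal difference was positive in several of these settings, up to 0.41, and not all of its calls were lower in KO.

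Genes with a low unadjusted p gathered near Pglyrp1 on chromosome 7. The excess within 10 Mb, in percentage points, was largest in the real split among all 35 (5.79, highest other 1.83). The shares near and elsewhere were 7.95% and 2.16% in the real split. They were 1.32% and 0.304%, a larger ratio, with KO 1, KO 2, KO 3 and WT 6 against the rest. The region was picked because it stood out in the real split, and the other splits were scored only there. This test therefore cannot decide on chance. The odds ratio of 3.92 was 2.77 (1.29 to 5.32) without WT libraries 6 and 9 and 2.81 without both pairs. With the myeloid and stromal covariate it was 14.4. It was 7.79 with a lower bound of 3.38 without KO libraries 3 and 4, so the excess was also present without them. The region was picked with all libraries in, and the bound takes neighbouring genes as independent. It therefore cannot decide on RNA of myeloid cells in those libraries. Of 346 windows of 20 Mb, 1 on chromosome 13 (15 to 35 Mb) ranked 3, with 9 of 88 genes at an unadjusted p under 0.01 (10.2%). The window with the strongest excess, with 17 of 199 genes (8.54%), held Pglyrp1 (rank 1), which restates the pattern. DNA of the donor strain linked to the targeted allele, strain variants that alter mapping and an effect of the deletion on its neighbours would all give this rank, so they cannot be told apart and stay open.

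Inhibitory receptor genes were higher in KO cells by 0.97 in list mean (log2 scale). The list was singled out after all lists were seen, and in 23 of the 35 splits the strongest list had a camera p as small at the preset correlation (on the -log10 scale 7.79, highest other 47.7), so chance cannot be excluded. The difference was 0.71 without KO libraries 3 and 4 (RNA of myeloid cells) and 0.50 without WT libraries 6 and 9 (a less activated, ribosome-rich cell state). The exact permutation p was 0.133 in both, and so few libraries cannot reach 0.05, so these explanations cannot be told apart from genotype. WT libraries 6 and 9 also had the highest list means of B and plasma cell markers, and RNA of such cells was not tested as an explanation. Loss of Pglyrp1 stays open as untested.

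Myeloid markers were high in KO libraries 3 and 4. Of 14 dendritic cell markers, a list that shares no gene with the myeloid one, 11 were also higher in both libraries than in each of the other 6, against 1.98 expected from the share among all genes tested (14.2%). Other lists exceeded that share as well, among them MC38 tumour and epithelial markers (8 of 20), fibroblast and endothelial markers (6 of 16), cholesterol and fatty acid synthesis (9 of 25) and apoptosis (8 of 20). The dendritic count is consistent with RNA of antigen-presenting cells in these sorts, perhaps beside that of other cells, although the gate on TCRβ and CD8 should remove them, and no biological explanation was tested. Apoe, abundant in many macrophages, was at 0.897 and 4.21 TPM there and at 3.47 to 49.6 TPM in WT libraries, and it lies 0.812 Mb from Pglyrp1.

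Besides Pglyrp1, which is absent from KO libraries by design, 2 genes passed the threshold, and 3 of the 35 splits gave as many (highest other 2), so chance cannot be excluded for that number. The 21 lists called with the preset correlation were matched by 1 of the 35 splits, the real one (highest other 18). A split that set KO 1, KO 2, WT 6 and WT 9 against the rest gave 2244 genes at an unadjusted p under 0.05, against 974 for genotype, which points to a structure of the samples that crosses the groups.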
